A study of Mus musculus with 42 samples.

How the data were processed

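Gene expression was measured in 42 RNA-seq libraries of CD4 T cells sorted by flow cytometry from mice, with Smart-seq2 amplification of 0.5 ng of total RNA, Nextera XT libraries and 50-bp paired-end reads. Per the labels, the sort took cells positive for Cd45, Cd3 and Cd4 and negative for Cd19, and parted them by Cxcr5, Gitr and Cd25 into effector T cells (Teff), regulatory T cells (Treg), follicular helper T cells (Tfh) and follicular regulatory T cells (Tfr). Teff were also gated as low in Cd62L and high in Cd44. Mice had received a mock injection (PBS) or 100 ug of ovalbumin with an adjuvant. MPLA in the labels is the adjuvant monophosphoryl lipid A, a ligand of Toll-like receptor 4. OC is not spelled out in the labels and was read, by exclusion from the protocol text, as ovalbumin with complete Freund's adjuvant.

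The authors deposited a table of read counts and a table of TPM (transcript abundances scaled by gene length to a common total) with 1 column per sample and 23337 gene symbols. Per the labels, the authors used TopHat2 2.0.9, HTSeq with no version given, and the genome build mm10. The annotation, the strand setting and the gene lengths behind the deposited TPM are not given in the sources used here. The count columns hold whole numbers with a different total in each library. Of the symbols, 20756 are current RefSeq symbols, and older ones are printed as the table has them (Folr4 is now Izumo1r, Pkm2 is Pkm). The table holds 0 of the 13 mitochondrial transcripts that were to be used as a list of RNA quality, so that list could not be tested. Coordinates are those of RefSeq genes on GRCm38 (mm10).

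The counts were analysed with edgeR 4.0.16 in R 4.3.3. Libraries were scaled by the trimmed mean of M values (TMM), genes were kept by filterByExpr with the groups (14493 genes), and a quasi-likelihood model with robust dispersions was fitted to the 12 groups of cell type and treatment, which left 30 residual degrees of freedom. The means of groups were compared in 20 contrasts. Tfr were compared with Treg within each treatment and as the mean of the 3 treatments, and with Tfh as the mean of the 3 treatments. Treg and Tfh were each compared with Teff as the mean of MPLA and OC, since Teff of PBS is 1 library. Treatments were compared within each cell type, and the difference of Tfr from Treg was compared between treatments as an interaction. Tests were two-sided, with Benjamini-Hochberg adjustment over all genes of a contrast and a threshold of 0.05. Expression is given as CPM, read counts scaled to a common total with the TMM factors, with SD over libraries. Log2 fold changes are those of the model, with a prior count, and are large but poorly bounded where a group lies near 0. For such genes CPM is given instead.

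There were 24 gene lists: sort gate, Treg core, Tfh program, Tfh-repressed, suppressive function, checkpoint and costimulatory receptors, T cell receptor induced, cell cycle, naive and central memory, Th1, Th2, Th17, cytokines, chemokine receptors and migration, interferon stimulated, glycolysis, cholesterol synthesis, immediate early and heat shock, mitochondrial transcripts, and 5 lists of other cells (B cell, plasma cell, myeloid and dendritic, CD8 and NK, and stroma with endothelium and erythroid). Some lists share members, so their calls are not independent of each other. Checkpoint receptors share Ctla4, Tigit and Lag3 with suppressive function, Pdcd1 and Icos with the Tfh program, and Tnfrsf4, Tnfrsf9 and Tnfrsf18 with Treg core. Genes of the sort gate also belong to other lists. Cxcr5 is in the Tfh program, Il2ra and Tnfrsf18 in Treg core, and Sell and Il2ra in Tfh-repressed. Lists were tested against all other genes with camera in limma 3.58.1, with a preset correlation of 0.01 between genes. An estimated correlation and fry were the alternatives, and p was adjusted over the lists of a contrast. fry asks whether the genes of a list move, on balance, one way and compares them with no other genes. The comparisons, the lists, the rule for naming genes and the first alternatives below were fixed before the data were examined.

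The text names genes by this rule. Among genes with adjusted p under 0.05 and mean CPM of at least 10 over the libraries compared, without receptor V, D and J segments, predicted genes, Rik names and ribosomal pseudogenes, it took the 10 largest increases and the 10 largest decreases (5 and 5 between treatments). For means over treatments, the sign had to be the same in each treatment. It added up to 4 members per list with the smallest p, the genes of the sort gate, and Foxp3, Bcl6, Prdm1 and Pdcd1 in each cell type comparison. Genes named outside the rule are said to be so.

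The alternatives were median-of-ratios size factors, no filter on low counts, a CPM of at least 5 in at least 3 samples, DESeq2 1.42.0 (Wald test), non-robust dispersions, a log2 fold change of at least 1, and limma-trend on the deposited TPM. TPM was taken as log2(TPM + 1) for genes with a TPM of at least 1 in at least 3 samples, as log2(TPM + 0.1), and with no filter. Further alternatives were a fit of only the groups compared, the mean of MPLA and OC only, a block on runs of donor numbers, and each library left out in turn. After the data were seen, 6 more were added. They were the called lists with each library left out in turn, the counts of each library drawn at random to 0.5 of their number, a batch term for runs of donor numbers with stromal transcripts, the 15 libraries of those runs alone, the 27 other libraries alone, and all libraries without 3 that stood apart in the principal components (Teff of MPLA with donor number 13, Treg of OC with 22 and Treg of PBS with 40).

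The procedure was tested on simulated data with known fold changes. For Tfr against Treg as the mean of treatments, edgeR found 17% of 2-fold and 46% of 4-fold changes with 4 false calls among 79. DESeq2 found 33% and 70% with 168 false calls among 288 (58.3%), and limma found 18% and 45% with 5 false calls among 79. For OC against PBS in Tfr, edgeR found 4% of 2-fold and 23% of 4-fold changes with 0 false calls among 27, and DESeq2 made 113 false calls among 160 (70.6%). For Tfr against Treg in PBS, edgeR found 0% and 21% with 0 false calls among 22, and DESeq2 made 154 false calls among 197 (78.2%). Other splits of the same libraries were counted with a faster fit of the same model. They exchanged cell types within each treatment, or treatments within a cell type. For the differences of Tfr from Treg they exchanged treatments within each cell type. Figures were drawn with matplotlib 3.10.9 in Python 3.11.15.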

Results

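The data were the read counts of 42 libraries of sorted CD4 T cells in 12 groups of cell type and treatment. Tfr, Treg and Tfh each had 4 libraries of MPLA, 4 of OC and 3 of PBS. Teff had 4 of MPLA, 4 of OC and 1 of PBS. Each library carried its own donor number, from 1 to 42, and replicates are named by it. The total count per library ran from 4475976 to 11380370 (median 7329690), and between 10155 and 12841 genes were detected. The 10 most abundant genes took 9.24% to 17.2% of the counts. Pairs of libraries from 1 group had a Pearson r of log2 CPM across genes between 0.776 and 0.913 (57 pairs, and genes are not independent replicates). The chi-square per degree of freedom of their counts against counting error alone lay between 35.8 and 171, so the tests take the spread from the libraries.

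Cell types parted along the principal components, and treatments did not. The first 2 components held 7.28% and 6.73% of the variance. Cxcr5, Il2ra (Cd25) and Tnfrsf18 (Gitr) parted the cells in the sort. Where gates differ in them, their differences check the sort and are no finding of their own. Cd45, Cd3 and Cd4 were part of every gate. Sell (Cd62L) and Cd44 were gated only in Teff, so the sort did not fix their differences between Tfr, Treg and Tfh. The gate did not use Foxp3. Foxp3, the transcription factor that defines regulatory T cells (chromosome X, 7579676 to 7595243), stood at 808 ± 172 CPM in Treg (SD, n = 11) and 475 ± 140 in Tfr (n = 11). It stood at 9.30 ± 16.4 in Tfh (n = 11) and 74.9 ± 46.7 in Teff (n = 9). Cxcr5, the chemokine receptor for B cell follicles, stood at 537 ± 141 CPM in Tfr and 79.6 ± 48.0 in Treg. Transcripts of stromal cells marked 4 of 11 runs of consecutive donor numbers, each of which held 1 library of each cell type present and 1 treatment. The summed CPM of 6 collagen and matrix genes (Col1a1, Col1a2, Col3a1, Dcn, Lum, Sparc) was 79.0 to 472 in these 15 libraries (227 ± 137) and 0 to 22.6 in the 27 others (2.78 ± 5.84). On component 4 (4.38% of the variance), the libraries of these runs lay at 18.2 or above, except Teff 13 at -43, and the 27 others at 7.8 or below. Per cell type, the 4 runs held 1 of 4 MPLA libraries, 1 of 4 OC libraries and, in Tfr, Treg and Tfh, 2 of 3 PBS libraries. The PBS library of Teff was also among them. Comparisons of a treatment with PBS were thus partly tied to these runs, and comparisons between cell types were balanced over them.

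**Figure D1:**
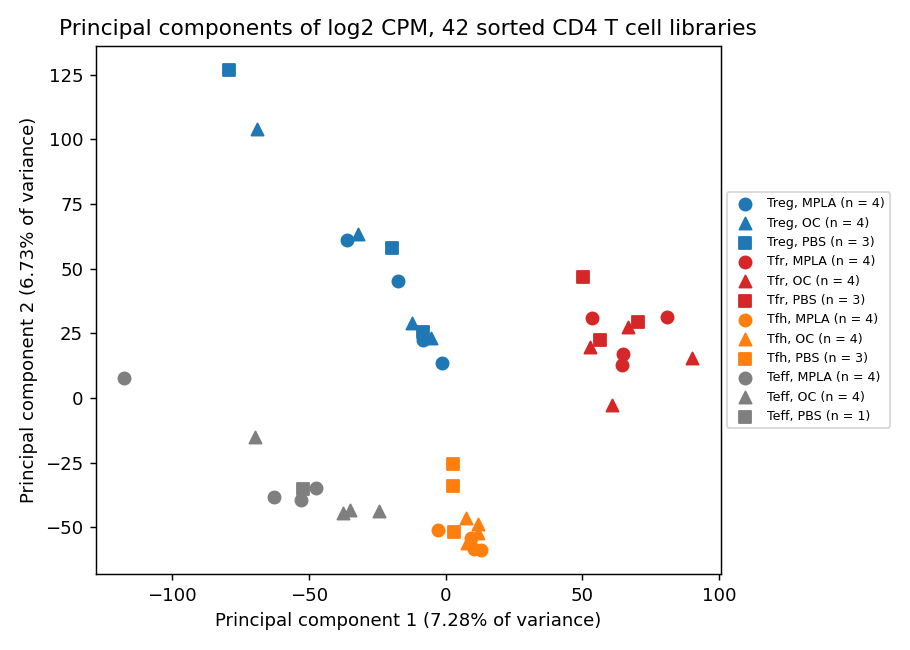
Libraries on the first 2 principal components of log2 CPM (percent of variance on each axis), with color for cell type and shape for treatment. Tfr, Treg, Tfh and Teff form separate groups, and within each group the treatments are mixed.

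Tfr were compared with Treg to ask how follicular regulatory cells differ from other regulatory T cells, as the mean over immunized (MPLA, OC) and mock-injected (PBS) mice. Tfr held more of the receptors Pdcd1 and Tigit and of the Tfh program list, and less of Klf2, S1pr1 and Sell. Pdcd1, which encodes the inhibitory receptor PD-1 (chromosome 1, 94038305 to 94052553), stood at 823 ± 217 CPM in Tfr and 78.1 ± 41.1 in Treg (SD, n = 11 and 11, log2 fold change 3.44, SE 0.24, adjusted p = 4.33e-14). Tigit, another inhibitory receptor (chromosome 16, 43626137 to 43665125), stood at 976 ± 261 and 85.5 ± 28.0 CPM (3.54, SE 0.29, adjusted p = 3.52e-12). Klf2, a transcription factor that drives exit from lymphoid tissue (chromosome 8, 72319062 to 72321654), was lower at 55.5 ± 14.7 against 507 ± 178 CPM (-3.20, SE 0.20, adjusted p = 1.76e-15). S1pr1, the receptor that guides this exit (chromosome 3, 115710433 to 115715055), was lower at 168 ± 41.7 against 684 ± 101 CPM (-2.05, SE 0.13, adjusted p = 1.59e-15). In all, 1149 of 14493 genes passed adjusted p under 0.05 as the mean of treatments, 584 higher and 565 lower in Tfr.

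The Tfh program list, which holds the gate gene Cxcr5, rose in Tfr, with 16 of 29 tested members higher and 1 lower (22 and 2 adjusted over the list alone, camera adjusted p = 2.59e-25). Bcl6, the transcription factor that directs follicular cells (chromosome 16, 23965050 to 23988866), stood at 283 ± 120 against 50.6 ± 24.2 CPM (2.56, SE 0.31, adjusted p = 6.16e-08). Maf, a transcription factor of follicular and cytokine-producing T cells, stood at 253 ± 75.6 against 40.0 ± 16.7 CPM (2.67, SE 0.24). The signalling adaptor Sh2d1a and the costimulatory receptor Icos had log2 fold changes of 1.80 (SE 0.15) and 1.65 (SE 0.16). Members near 0 in Treg were the follicular transcription factor Ascl2 (24.3 against 0.0592 CPM, adjusted p = 7.58e-05), the myeloid transcription factor Cebpa (76.5 against 1.06 CPM, adjusted p = 1.65e-06), the secreted inhibitor Sostdc1 (103 against 0.834 CPM, adjusted p = 0.000212) and Il4 (15.4 against 2.15 CPM, adjusted p = 5.84e-06). Tfh-repressed genes fell, with 7 of 13 members lower and 1 higher (8 and 3 adjusted over the list alone; adjusted p = 3.31e-11). Selplg, the ligand of selectins (-1.56, SE 0.17), was among them. Genes of naive and central memory cells fell as a group, with 13 of 16 lower and 0 higher (14 lower adjusted over the list alone; adjusted p = 2.31e-35). Ly6c1 stood at 6.49 ± 5.00 against 283 ± 79.2 CPM, though reads of 50 bp may not part it from Ly6c2, and the transcription factor Foxp1 had a log2 fold change of -1.32 (SE 0.12).

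Suppressive function genes rose as a group (5 of 21 higher and 1 lower, 10 and 2 adjusted over the list alone; adjusted p = 6.15e-07). So did checkpoint and costimulatory receptors (9 of 25 higher and 1 lower, 12 and 1 adjusted over the list alone; adjusted p = 1.50e-08). Lag3, an inhibitory receptor that binds MHC class II, stood at 380 ± 233 CPM in Tfr and 47.7 ± 31.7 in Treg (3.04, SE 0.42). Il1r2, the decoy receptor for interleukin 1, stood at 248 ± 115 against 12.4 ± 23.1 CPM (4.56, SE 1.03, adjusted p = 0.00315). Nt5e, the ectoenzyme CD73, had a log2 fold change of 1.38 (SE 0.23). The Treg core list had 7 members higher and 5 lower of 24 (10 and 5 adjusted over the list alone), and no shift as a group was called (camera adjusted p = 0.101, median log2 fold change 0.40, mean -0.04). Its member Il2ra, part of the gate, stood at 133 ± 59.2 against 666 ± 107 CPM, and Ecm1 had a log2 fold change of -1.82 (SE 0.27). Foxp3 itself was 475 ± 140 CPM in Tfr and 808 ± 172 in Treg and did not pass (-0.73, SE 0.38, adjusted p = 0.303). It passed when only these groups were fitted (-0.75, adjusted p = 0.00108). Prdm1, which encodes the repressor Blimp1, stood at 53.9 ± 36.6 against 26.5 ± 29.6 CPM and did not pass (1.67, SE 0.66, adjusted p = 0.126), and it did with DESeq2 (adjusted p = 0.0394) and with TPM (1.59, adjusted p = 0.0145).

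Glycolysis genes rose, with 5 of 17 higher and 0 lower (7 adjusted over the list alone; adjusted p = 1.50e-05). Hif1a, the transcription factor of the response to low oxygen (chromosome 12, 73901324 to 73947554), stood at 1662 ± 282 against 344 ± 146 CPM (2.28, SE 0.15, adjusted p = 8.98e-15). The glycolytic enzymes Tpi1, Gapdh and Pkm2 had log2 fold changes of 1.18 (SE 0.24), 0.61 (SE 0.12) and 0.57 (SE 0.12). T cell receptor induced genes had 5 of 20 higher and 2 lower (6 and 3 adjusted over the list alone; adjusted p = 0.0142), with adjusted p = 0.104 with an estimated correlation. Egr1 (1.57, SE 0.26), Nfatc1 (1.53) and Bhlhe40 (2.92, SE 0.59) were higher and Myc (-1.30, SE 0.27) was lower. Cell cycle genes had 4 of 30 higher, adjusted over the list alone also 4 (adjusted p = 0.00179), with adjusted p = 0.233 with an estimated correlation and 0.0984 without Tfr 38. Ccnb2, a cyclin of mitosis, stood at 34.4 ± 47.5 against 1.84 ± 2.98 CPM (not called with MPLA and OC only, 3.19, adjusted p = 0.134), and the replication licensing gene Mcm6 had a log2 fold change of 1.53 (SE 0.21). Cytokine genes had 4 of 16 higher and 2 lower (adjusted p = 0.0128, and 0.0325 with an estimated correlation). Tnfsf14 stood at 33.3 ± 25.4 against 2.07 ± 3.89 CPM, and the lymphotoxin genes Ltb (-0.76, SE 0.12) and Lta (-1.42, SE 0.31) were lower. Cholesterol synthesis genes fell as a group with 0 of 18 past the threshold alone by edgeR (adjusted p = 0.000349, and 0.00915 with an estimated correlation).

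Interferon stimulated genes had 7 of 35 lower and 2 higher (adjusted p = 0.0159), with adjusted p = 0.192 with an estimated correlation. The guanylate-binding relatives Ifi47 (-1.32, SE 0.19) and Igtp (-1.09, SE 0.19) were lower, and Gbp1, whose family shares sequence, stood at 0.155 against 34.7 CPM. The camera test called no shift of Th1 (4 of 19 higher, adjusted p = 0.0575), Th2 (3 of 9 higher and 1 lower, adjusted p = 0.243), Th17 (1 of 10 higher, adjusted p = 0.721), chemokine receptors and migration (6 of 24 higher and 5 lower, adjusted p = 0.556, median 0.28, mean -0.03) or immediate early and heat shock genes (2 of 20 higher and 2 lower, adjusted p = 0.721). The Th1 chemokine receptor Cxcr3 had a log2 fold change of 2.18, and the interleukin 4 receptor Il4ra one of -1.73 (SE 0.39). Among the lists of other cells, B cell genes had 1 of 21 higher and 1 lower (adjusted p = 0.556), plasma cell genes 0 of 7 (adjusted p = 0.546), myeloid and dendritic genes 1 of 23 lower (adjusted p = 0.193) and stroma genes 1 of 13 lower (adjusted p = 0.556). The B cell receptor gene Cd22 stood at 32.3 ± 16.2 against 1.66 ± 4.09 CPM. CD8 and NK genes had 4 of 14 lower and 1 higher (adjusted p = 0.0334), with adjusted p = 0.104 with an estimated correlation. Treg 40 held 586 CPM of these genes and the other Treg libraries at most 161, and the call was lost without Treg 40 (0.243), 10 (0.139), 22 (0.147) or 30 (0.0651) or Tfr 35 (0.0719) or 42 (0.0726). The sort gate list had 7 of 11 higher and 2 lower (adjusted p = 3.69e-06), including Cxcr5 (2.77), Tnfrsf18, which encodes Gitr (0.64), Cd44 (0.92) and Sell, which encodes Cd62L (-3.43). Cd44 and Sell were gated only in Teff, so the sort did not fix their differences here.

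Further genes with large changes were near 0 on 1 side. The amino acid transporter Slc7a10 (chromosome 7, 35186095 to 35201116) stood at 76.3 ± 37.5 CPM in Tfr and 1.65 ± 5.11 in Treg (adjusted p = 4.65e-06). Fam81a stood at 25.9 against 0.352 CPM, Atp1a3, a subunit of the sodium pump, at 65.7 against 0.623, and Sccpdh at 191 against 8.97. Lower in Tfr were Gpr146 (6.42 against 95.2 CPM), the sialyltransferase St8sia6 (7.59 against 107 CPM) and the receptor Sorcs2 (0.0377 ± 0.0646 against 24.7 ± 40.7 CPM). Of the 1149 genes, 774 had a fold of at least 2, and 2716 genes had an unadjusted p under 0.05 (725 are expected by chance). In the 27 libraries of runs without stromal transcripts the count was 655 (237 higher and 418 lower), and in the 15 others it was 58. Of the genes named above, Il1r2 (5.50, adjusted p = 0.109), Sostdc1 (6.70, 0.104), Bhlhe40 (2.54, 0.0535), Myc (-1.14, 0.0689), Ccnb2 (4.10, 0.307) and Fam81a (5.89, 0.144) did not pass in the 27 libraries. With MPLA and OC only, the immunized mice, the count was 751, and St8sia6 did not pass (-3.34, adjusted p = 0.081). The share of higher genes was 50.8% with counts and 69.6% with the deposited TPM, which moved the median of all genes by 0.14.

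**Figure D2:**
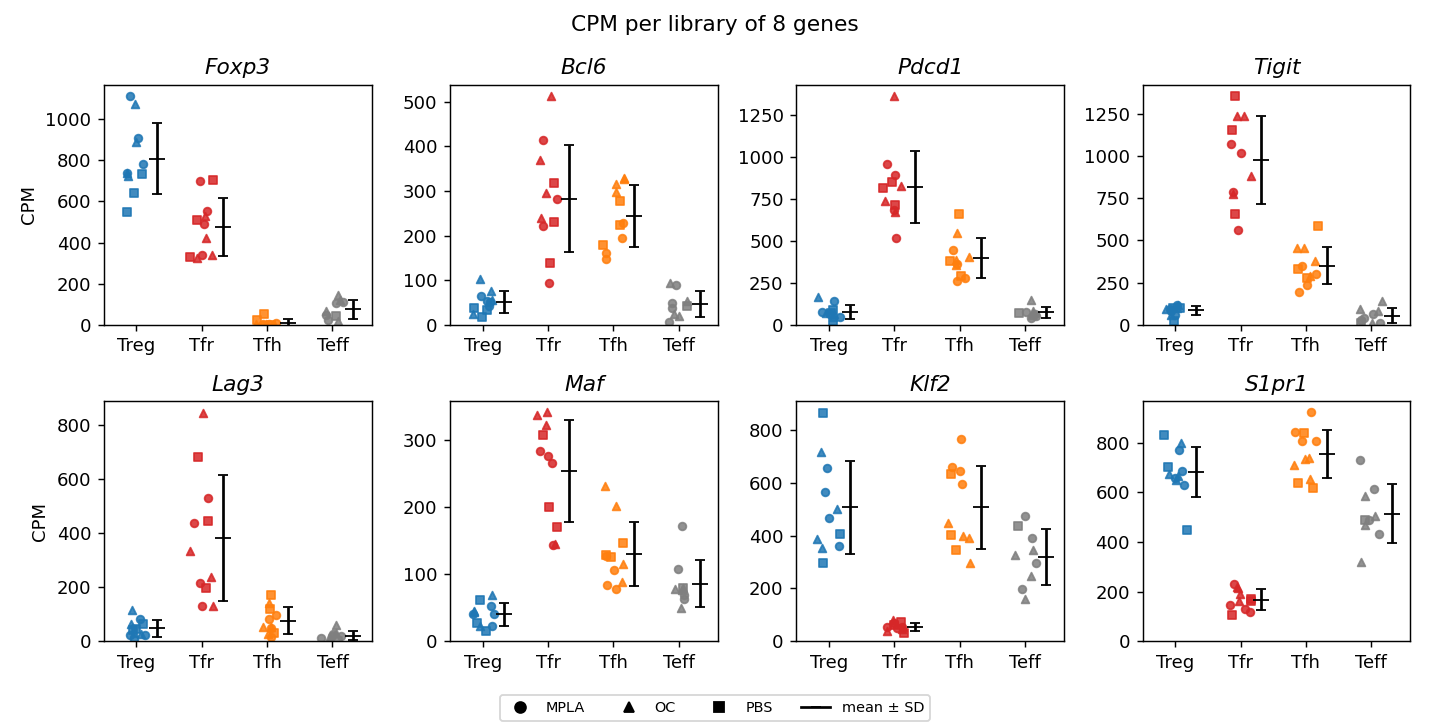
CPM of 8 genes in each library (points, shape for treatment) by cell type, with mean and SD as bars. Foxp3 lies high in Treg and Tfr, Bcl6 in Tfr and Tfh, Pdcd1, Tigit and Lag3 are highest in Tfr, and Klf2 and S1pr1 are lowest in Tfr.

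Within each treatment, Pdcd1, Tigit, Bcl6 and Hif1a were higher and Klf2 and Sell lower. Pdcd1 had log2 fold changes of 3.21 (adjusted p = 6.19e-07) in MPLA, 3.37 (adjusted p = 1.92e-07) in OC and 3.73 (adjusted p = 1.37e-06) in PBS. Its CPM in Tfr and Treg was 763 ± 202 and 82.7 ± 40.5 in MPLA (n = 4 and 4), 902 ± 315 and 87.1 ± 52.8 in OC (n = 4 and 4), and 796 ± 69.7 and 59.9 ± 33.2 in PBS (n = 3 and 3). Bcl6 was higher by 2.26 in MPLA (adjusted p = 0.00774), 2.47 in OC (adjusted p = 0.00241) and 2.95 in PBS (adjusted p = 0.00304). Tigit was higher by 3.30, 3.49 and 3.83, and Hif1a by 2.44, 2.14 and 2.27. Klf2 had -3.19, -3.15 and -3.25, and Sell -2.74, -4.20 and -3.36. Foxp3 had -0.77 (adjusted p = 0.729), -1.09 (adjusted p = 0.471) and -0.32 (adjusted p = 0.996), and with only the groups compared it passed in OC (-1.08, adjusted p = 0.0349). The Tfh program list had 12, 12 and 10 of 29 members higher in MPLA, OC and PBS and 0 lower (16, 18 and 16 higher adjusted over the list alone), and naive and central memory genes had 10, 11 and 10 of 16 lower. Th1 genes were called higher in PBS (1 of 19 past the threshold, adjusted p = 0.00246, 0.0408 with an estimated correlation, and 0.0509 without Tfr 42) and not in MPLA or OC (0.0926 and 0.517). The Treg core list was called higher in MPLA (2 of 24 higher and 2 lower, adjusted p = 0.0453) and not in OC or PBS (0.517 and 0.32). That call was lost with an estimated correlation (0.231) and without Treg 2 or 10 or Tfr 12 or 16 (0.139, 0.108, 0.0875 and 0.081).

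By treatment, 193 genes passed in MPLA (85 higher and 108 lower), 262 in OC (88 and 174) and 179 in PBS (82 and 97). The treatments share no library, and 80 genes passed in all 3, 28 higher and 52 lower. Among them, chosen after their values were seen, were Bcl6, Hif1a, Icos, Lag3, Maf, Nfatc1, Pdcd1, Sh2d1a and Tigit (higher) and Foxp1, Klf2, Ly6c1, S1pr1, Selplg, Ecm1 and Il2ra (lower). Many of the 52 lower genes were ribosomal protein genes, such as Rpl10a, Rpl32, Rplp0 and Rps3, which are taken up further below. MPLA and OC shared 119 genes, MPLA and PBS 101 and OC and PBS 102, and each shared gene moved the same way. In MPLA and OC, 39 were higher in both (0.516 expected) and 80 lower in both (1.30 expected). DESeq2 called 662, 693 and 890 genes and limma with TPM 377, 490 and 403. The share of higher genes was 44.0%, 33.6% and 45.8% with counts and 59.9%, 65.7% and 66.7% with TPM, which moved the median of all genes by 0.20 in OC. Single libraries moved these counts. MPLA fell to 122 genes without Treg 14, OC to 146 without Treg 22 and 161 without Tfr 24, and PBS to 104 without Tfr 35 and 66 without Treg 40. In MPLA, Bcl6 did not pass without Tfr 4 (1.91, adjusted p = 0.0541). The 27 libraries gave 134, 228 and 134 genes, of which 107, 176 and 36 were among those called with all libraries, and PBS then had 1 library per cell type. The 15 others gave 0, 0 and 26 genes by edgeR with 1 library per cell type in MPLA and OC. With only the groups compared, OC gave 107 genes and PBS 13, and Bcl6, Klf2 and Sell did not pass in PBS (2.90, -3.28 and -3.41, adjusted p = 0.0752, 0.053 and 0.0879). Bcl6 also did not pass in PBS in the 27 libraries (3.67, adjusted p = 0.114).

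The difference of Tfr from Treg was also compared between treatments. Ncaph2, a subunit of condensin II (chromosome 15, 89355719 to 89372850), had a smaller difference in MPLA than in PBS (-2.14, SE 0.39, adjusted p = 0.0402). The call was lost without any of 11 of the 14 libraries (donor numbers 2, 4, 6, 8, 10, 14, 16, 36, 38, 40 and 42, adjusted p between 0.0726 and 0.23), where the difference stayed between -2.15 and -1.92. By edgeR, 0 genes passed for OC minus PBS and for OC minus MPLA. Unadjusted p was under 0.05 for 1052 genes in OC minus PBS, 952 in MPLA minus PBS and 864 in OC minus MPLA. DESeq2 called 206, 238 and 162 genes and limma with TPM 1, 3 and 3. The Th1 list was lower in OC minus PBS (adjusted p = 0.000435, and adjusted p = 0.0643 with an estimated correlation) and in OC minus MPLA (adjusted p = 0.0256, and adjusted p = 0.158 with an estimated correlation). In OC minus MPLA, Tfh-repressed genes (adjusted p = 0.00232, and 0.0153 with an estimated correlation) and chemokine receptors and migration (adjusted p = 0.0256, and 0.0285 with an estimated correlation) were lower, and so were interferon stimulated genes (adjusted p = 0.0256, and adjusted p = 0.321 with an estimated correlation). Cell cycle genes were lower in OC minus PBS (adjusted p = 0.0032, and adjusted p = 0.681 with an estimated correlation) and in MPLA minus PBS (adjusted p = 5.8e-05, and adjusted p = 0.926 with an estimated correlation). Single libraries carried some of these calls. Cell cycle genes lost both without Tfr 38 (0.79 and 0.372), and OC minus PBS also without Treg 18 (0.224). In OC minus MPLA, chemokine receptors were not called without Treg 2 or 30 or Tfr 12 or 28 (0.0653, 0.109, 0.106 and 0.0603), Th1 without Treg 6 or 30 or Tfr 12 or 28 (0.0755, 0.347, 0.106 and 0.0603), and interferon stimulated genes without Treg 2, 14 or 30 or Tfr 8, 12, 24 or 28 (0.056 to 0.347). With the stromal runs as a batch term the counts of genes were 0, 1 and 0, in the 27 libraries 51, 62 and 0, and in the 15 others MPLA minus PBS gave 0. Leaving out Treg 33 gave 9 genes for OC minus PBS and 5 for MPLA minus PBS, leaving out Tfr 35 gave 1 and 2, leaving out Treg 36 or 30 gave 1 for OC minus PBS, and leaving out Treg 18 or 30 gave 1 for OC minus MPLA.

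**Figure D3:**
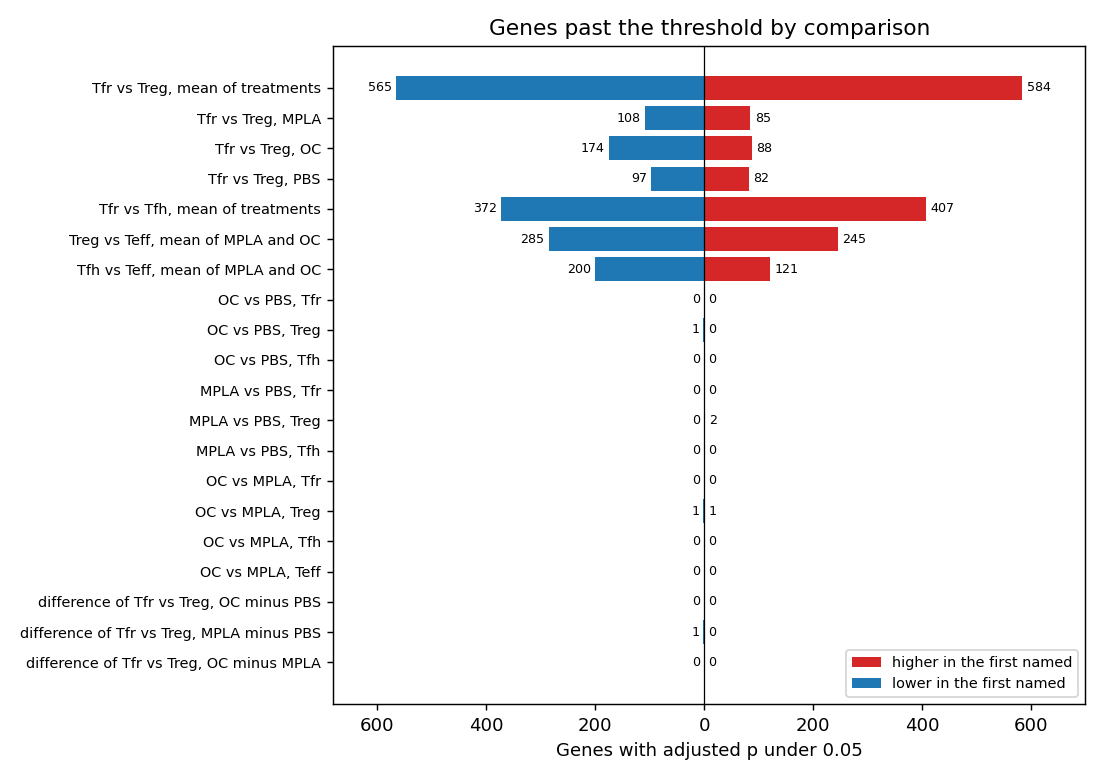
Genes past adjusted p under 0.05 in each of the 20 comparisons, with those higher in the first named group to the right and those lower to the left. Comparisons of cell types call between 179 and 1149 genes, and comparisons of treatments and of differences at most 2.

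Tfr were compared with Tfh, the other cells gated on Cxcr5, to separate what is regulatory from what is follicular. Tfr held more of the Treg core list and of the receptors Tnfrsf9 and Tnfrsf4, and less of the transcription factor Tcf7. Tnfrsf9, the costimulatory receptor 4-1BB (chromosome 4, 150920155 to 150946104), stood at 674 ± 200 CPM in Tfr and 36.4 ± 18.4 in Tfh (SD, n = 11 and 11, log2 fold change 4.14, SE 0.30, adjusted p = 7.13e-14). Tnfrsf4, the receptor OX40 (chromosome 4, 156013595 to 156016613), stood at 1126 ± 351 against 61.3 ± 30.4 CPM (4.14, SE 0.26, adjusted p = 1.06e-15). Foxp3 was higher by 6.43 (SE 0.50, adjusted p = 7.17e-12). Tcf7, which sustains Tfh and memory cells (chromosome 11, 52246527 to 52283383), was lower at 355 ± 90.8 against 1245 ± 147 CPM (-1.79, SE 0.15, adjusted p = 8.80e-12). In all, 779 genes passed, 407 higher and 372 lower in Tfr.

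The Treg core list had 21 of 24 members higher and 0 lower (22 adjusted over the list alone, adjusted p = 9.30e-66). Its members Il2ra and Tnfrsf18 belong to the gate, which checks the sort and is no finding for these. Ctla4, the inhibitory receptor that competes with Cd28 (chromosome 1, 60909025 to 60915832), stood at 492 ± 91.8 against 50.6 ± 24.6 CPM (3.37, SE 0.26). Capg, an actin-capping protein, was higher by 2.83 (SE 0.16), and Lrrc32, which holds latent TGF-beta at the surface, stood at 127 ± 91.4 against 0.613 ± 0.361 CPM. Suppressive function genes had 16 of 21 higher and 0 lower (17 adjusted over the list alone; adjusted p = 1.48e-25). The chemokine receptor Ccr8 stood at 135 ± 40.8 against 2.08 ± 3.27 CPM, Prdm1 at 53.9 ± 36.6 against 2.15 ± 2.61 (4.66, SE 0.76, adjusted p = 3.50e-05) and the interleukin 1 antagonist Il1rn at 47.7 ± 36.4 against 1.04 ± 3.34. Checkpoint and costimulatory receptors had 10 of 25 higher and 4 lower (12 and 4 adjusted over the list alone; adjusted p = 1.42e-08), and T cell receptor induced genes 6 of 20 higher and 1 lower (8 and 1 adjusted over the list alone; adjusted p = 5.64e-08). Pdcd1 was higher by 1.03 (SE 0.22, adjusted p = 0.00145), Bhlhe40 by 3.22 and Nfatc1 by 0.67. Glycolysis genes had 6 of 17 higher and 1 lower (8 and 2 adjusted over the list alone; adjusted p = 0.000334). Hif1a was higher by 1.43 (adjusted p = 1.33e-09) and Tpi1 by 1.34, and lactate dehydrogenase Ldha was lower (-0.55, SE 0.11).

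Naive and central memory genes had 11 of 16 lower and 0 higher (12 lower adjusted over the list alone; adjusted p = 9.82e-27). Klf2 (-3.14, SE 0.20), S1pr1 (-2.18, SE 0.13) and the actin crosslinker Actn1 (-2.84, SE 0.29) were among them. The Tfh program list moved both ways, with 6 of 29 higher and 7 lower, and no shift was called (adjusted p = 0.518, median 0.15, mean -0.10). The transcription factor Batf (1.49, SE 0.21) was higher, the adhesion receptor Slamf6 (-1.46, SE 0.14) and the helper ligand Cd40lg (-2.12, SE 0.28) were lower, and Bcl6 did not pass (283 ± 120 against 244 ± 68.5 CPM, 0.21, SE 0.29, adjusted p = 0.942). Tfh-repressed genes had 7 of 13 lower and 3 higher (8 and 3 adjusted over the list alone; adjusted p = 0.00167). Their median was -0.83 and their mean 0.07, since the interleukin 2 receptor chains Il2rb (1.95, SE 0.16) and Il2ra and Prdm1 were higher while the oxysterol receptor Gpr183 (-1.10, SE 0.16) was lower. Chemokine receptors and migration had 7 of 24 lower and 2 higher (8 and 4 adjusted over the list alone; adjusted p = 0.0152, and 0.0165 with an estimated correlation; median -0.28, mean 0.27). Cholesterol synthesis genes fell with 1 of 18 past the threshold (adjusted p = 0.000163).

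The calls of cell cycle genes (1 of 30 higher, adjusted p = 0.0324, and adjusted p = 0.452 with an estimated correlation), Th1 (1 of 19 lower, adjusted p = 0.0451, and adjusted p = 0.155 with an estimated correlation) and immediate early and heat shock genes (4 of 20 higher, adjusted p = 0.014, and adjusted p = 0.155 with an estimated correlation) were lost with an estimated correlation. Cell cycle genes were also not called without Tfr 38 (0.656), Tfr 28 (0.076) or Tfh 11, 15 or 34 (0.0719, 0.0631 and 0.0767), nor Th1 without any of 10 of the 22 libraries (Tfh 3, 7, 23, 31 or 37, Tfr 8, 16, 28, 35 or 38, 0.0518 to 0.122). The immediate early list had a median of 0.07 with counts and -0.04 with TPM, where the median of all genes was -0.05 with log2(TPM + 1). Myeloid and dendritic genes had 3 of 23 lower (2 higher and 6 lower adjusted over the list alone; adjusted p = 0.0119, and adjusted p = 0.155 with an estimated correlation and 0.0555 without Tfh 31), among them transcripts that were high in some Tfh libraries of OC (S100a8, between 3.88 and 1201 CPM, named after its values were seen). No shift was called for Th2 (0 of 9 by edgeR, adjusted p = 0.444), Th17 (1 of 10 lower, adjusted p = 0.148), cytokines (3 of 16 higher, adjusted p = 0.444), interferon stimulated (3 of 35 higher and 1 lower, adjusted p = 0.923), B cell (2 of 21 lower, adjusted p = 0.0925), plasma cell (0 of 7, adjusted p = 0.941), CD8 and NK (1 of 14 higher and 1 lower, adjusted p = 0.518) or stroma genes (1 of 13 lower, adjusted p = 0.949). The sort gate genes Il2ra (5.48), Tnfrsf18 (2.88) and Sell (-1.11, adjusted p = 0.0111) passed. Of these, Sell was gated only in Teff.

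Genes near 0 in Tfh were Slc7a10 (76.3 against 0.319 CPM), Fam81a (25.9 against 0.0532), Noxa1 (41.8 against 0.0796), Rragd, a GTPase of nutrient sensing (28.7 against 0.123), the muscle protein Neb (87.2 against 0.969) and the lectin receptor Klrg1 (64.0 against 0.532). Near 0 in Tfr were Tgfb3, which encodes a TGF-beta (0.0547 against 37.4 ± 17.3 CPM), the contractile protein Smtn (0.910 against 85.4) and the transporter Slc16a5 (1.15 against 53.1). Of the 779 genes, 557 had a fold of at least 2, and 2307 genes had an unadjusted p under 0.05. DESeq2 called 1270 and the mean of MPLA and OC gave 486. The 27 libraries gave 501 genes, 277 of them among the 779, and Pdcd1 did not pass there (0.90, adjusted p = 0.135), nor did Il1rn, Fam81a and Nfatc1 (8.68, 7.36 and 0.66, adjusted p = 0.0988, 0.0987 and 0.0557). The 15 libraries gave 68. Sell did not pass without Tfh 34 (-0.81, adjusted p = 0.081), and Ldha did not with MPLA and OC only (-0.35, adjusted p = 0.135).

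**Figure D4:**
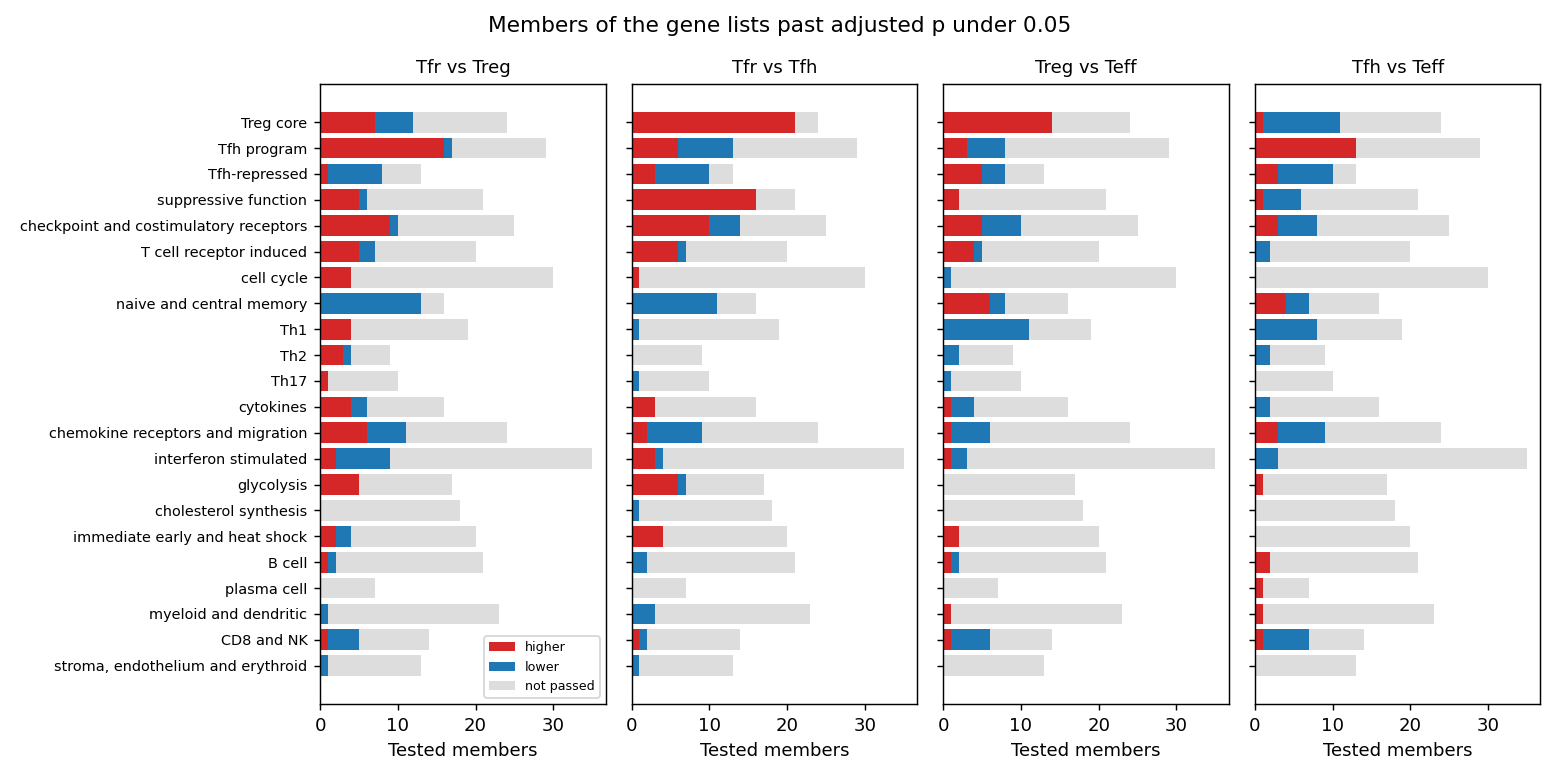
Tested members of 22 gene lists past adjusted p under 0.05 (higher in red, lower in blue) and not past it (grey) in the 4 comparisons of cell types averaged over treatments. The Treg core list is higher in Tfr than in Tfh with 21 of 24 members, and the naive and central memory list is lower in Tfr than in Treg with 13 of 16.

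Treg and Tfh were each compared with Teff, the effector cells gated as negative for Cxcr5, Gitr and Cd25, over MPLA and OC. Of 19 tested Th1 genes, 11 were lower in Treg than in Teff and 8 lower in Tfh than in Teff, and Id2 and Cxcr6 were lower in both. Id2, an inhibitor of E proteins (chromosome 12, 25093799 to 25096092), stood at 2002 ± 453 CPM in Teff and 114 ± 115 in Treg (SD, n = 8 and 8, log2 fold change -4.49, SE 0.26, adjusted p = 5.29e-16). Cxcr6, a chemokine receptor of tissue-homing T cells (chromosome 9, 123806477 to 123811754), stood at 1693 ± 508 CPM in Teff and 23.3 ± 41.4 in Treg (adjusted p = 4.68e-06). Foxp3 was higher in Treg, at 871 ± 153 against 79.0 ± 48.2 CPM (3.47, SE 0.48, adjusted p = 6.31e-06). For Treg against Teff, 530 genes passed, 245 higher and 285 lower, 403 with a fold of at least 2 (2255 at unadjusted p under 0.05, and 1072 with DESeq2).

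The Treg core list, which holds the gate genes Il2ra and Tnfrsf18, rose in Treg with 14 of 24 higher and 0 lower (17 adjusted over the list alone, adjusted p = 1.09e-33). The G protein receptor Gpr83 stood at 272 ± 76.0 against 6.67 ± 12.3 CPM, Ctla4 at 357 ± 106 against 59.2 (2.57, SE 0.29), and Ecm1 (3.17, SE 0.33), Capg (1.63, SE 0.18), Folr4, the folate receptor relative of regulatory cells (1.36, SE 0.14), and Tnfrsf4 (2.33, SE 0.27) were also higher. Th1 genes fell with 11 of 19 lower and 0 higher (16 lower adjusted over the list alone; adjusted p = 4.13e-23). Nkg7, a granule protein (-3.75, SE 0.34), the chemokine Ccl5 (-5.03, SE 0.73), Cxcr3 (-3.03, SE 0.34) and Tbx21, the transcription factor T-bet (14.7 ± 35.3 against 227 ± 44.3 CPM), were among them. CD8 and NK genes had 5 of 14 lower and 1 higher (9 and 2 adjusted over the list alone; adjusted p = 4.35e-06), with Klrb1c (1.70 against 278 CPM), Klrk1 (1.85 against 130) and the chemokine Xcl1 (3.02 against 108), where the Klr families share sequence. Zbtb16, the transcription factor PLZF of innate-like T cells (chromosome 9, 48651797 to 48836225), stood at 0.0541 against 55.0 ± 42.0 CPM, and the lipid transporter Atp8a2 at 0.189 against 153 ± 70.4. Chemokine receptors and migration had 5 of 24 lower and 1 higher (6 and 2 adjusted over the list alone; adjusted p = 4.35e-06), with the integrin Itgb1 at -2.22 (SE 0.17). T cell receptor induced genes had 4 of 20 higher and 1 lower (9 and 2 adjusted over the list alone; adjusted p = 4.35e-06), and suppressive function genes 2 of 21 higher and 0 lower (8 and 3 adjusted over the list alone; adjusted p = 0.00839). Th2 genes had 2 of 9 lower (1 higher and 5 lower adjusted over the list alone; adjusted p = 0.00314), with Il4 at 2.88 against 35.3 CPM. In the gate, Sell (3.56), Il2ra (3.06) and Tnfrsf18 (1.10) were higher and Cd44 (-1.44) lower.

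Calls lost with an estimated correlation for Treg against Teff were naive and central memory (6 of 16 higher and 2 lower, adjusted p = 0.00581, and adjusted p = 0.0503 with an estimated correlation), checkpoint receptors (5 of 25 higher and 5 lower, adjusted p = 0.0184, and adjusted p = 0.138 with an estimated correlation), Th17 (1 of 10 lower, adjusted p = 0.0199, and adjusted p = 0.151 with an estimated correlation), cell cycle (1 of 30 lower, adjusted p = 0.0212, and adjusted p = 0.404 with an estimated correlation), cytokines (1 of 16 higher and 3 lower, adjusted p = 0.0228, and adjusted p = 0.0536 with an estimated correlation) and B cell genes (1 of 21 higher and 1 lower, adjusted p = 0.0138, and adjusted p = 0.337 with an estimated correlation). The retinoid-related receptor Rora (-1.88, SE 0.47) and Tnfsf14 (0.962 against 83.6 CPM) were lower in Treg. Without 1 library, cell cycle genes were not called without Teff 5 or 29 or Treg 22 or 26 (0.116, 0.108, 0.0681 and 0.0601), cytokines without Teff 9 or Treg 26 (0.0645 and 0.0824) and Th17 without Treg 10 (0.0501). The cytokine list had a median of -0.09 with counts and 0.01 with TPM, where the median of all genes was 0.0057 with log2(TPM + 1). Bcl6, Prdm1 and Pdcd1 did not pass (0.32, 0.25 and 0.24, adjusted p = 0.816, 1 and 0.819).

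For Tfh against Teff, 321 genes passed, 121 higher and 200 lower, 244 with a fold of at least 2 (1795 at unadjusted p under 0.05, and 696 with DESeq2). The Tfh program list, which holds the gate gene Cxcr5, rose with 13 of 29 higher and 0 lower (17 adjusted over the list alone, adjusted p = 6.90e-30). Bcl6 stood at 250.1 ± 76.5 CPM in Tfh and 46.5 ± 31.6 in Teff (n = 8 and 8, 2.37, SE 0.35, adjusted p = 1.18e-05), Pdcd1 at 381 ± 91.5 against 73.7 ± 32.5 (2.40, SE 0.26) and Tcf7 at 1282 ± 159 against 464 ± 136 (1.47, SE 0.18). Cxcr5 (3.88), Tigit (2.60, SE 0.32) and the transcription factor Tox (1.84, SE 0.21) were higher, and so were Actn1 (1.66, SE 0.32), Smtn (112 against 6.79 CPM) and Eomes (19.5 ± 14.0 against 0.123 CPM). Treg core genes had 10 of 24 lower and 1 higher (14 and 2 adjusted over the list alone; adjusted p = 3.53e-13), with Foxp3 at 2.83 ± 3.08 against 79.0 ± 48.2 CPM. Th1 genes had 8 of 19 lower and 0 higher (13 and 2 adjusted over the list alone; adjusted p = 2.76e-16), CD8 and NK genes 6 of 14 lower and 1 higher (10 and 1 adjusted over the list alone; adjusted p = 3.42e-08) and Tfh-repressed genes 7 of 13 lower and 3 higher (7 and 4 adjusted over the list alone; adjusted p = 1.75e-05). Id2 (128 ± 50.1 against 2002 ± 453 CPM), Il2rb (-2.53, SE 0.18), Il7r, the interleukin 7 receptor (-2.27, SE 0.29), Nkg7 (-3.70, SE 0.34), Ccl5 (-3.99, SE 0.69) and Cxcr6 (-4.52, SE 0.84) were lower. Prdm1 stood at 2.24 against 23.8 CPM (adjusted p = 0.0137), Ccr2 at 1.07 against 245, Zbtb16 at 0.0858 against 55.0, Xcl1 at 2.16 against 108 and Klrk1 at 2.29 against 130. Suppressive function genes (5 of 21 lower and 1 higher, adjusted p = 0.00784), Th2 genes (2 of 9 lower, adjusted p = 0.00291, with Gata3 at -0.92, SE 0.21), chemokine receptors and migration (6 of 24 lower and 3 higher, adjusted p = 0.00387) and interferon stimulated genes (3 of 35 lower, adjusted p = 0.000104) fell. B cell genes rose with 2 of 21 higher (9 and 1 adjusted over the list alone; adjusted p = 4.35e-05, and adjusted p = 0.0939 with an estimated correlation). Tfh 31 held 2206 CPM of these genes and 1065 of plasma cell genes, against 161 to 817 and 85.1 to 314 in the 7 other Tfh libraries compared, and without it the call held (0.0033). The 27 libraries gave 394 genes for Treg and 216 for Tfh against Teff, and the 15 others 77 and 21 with 2 libraries per cell type. The share of higher genes for Tfh was 37.7% with counts and 55.5% with TPM, which moved the median of all genes by 0.19.

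OC was compared with PBS to ask what OC, read as ovalbumin in complete Freund's adjuvant, changed within each cell type. Only Trp53i13, named after its values were seen (chromosome 11, 77508099 to 77515921), passed in Treg, at 0.142 ± 0.284 CPM in OC and 18.7 ± 7.11 in PBS (n = 4 and 3, adjusted p = 0.0139). Its CPM in Treg of OC was 0 in 3 libraries and 0.593 in the other. The call was lost without Treg 18, 22 or 26 (adjusted p = 0.0556, 0.0755 and 0.0854). In Tfr and Tfh, edgeR called 0 genes. Unadjusted p was under 0.05 for 996 genes in Tfr, 1115 in Treg and 635 in Tfh, against 725 expected by chance. DESeq2 called 200 genes in Tfr, 240 in Treg and 111 in Tfh, and limma with TPM 1, 5 and 0. Glycolysis genes were lower in Tfh of OC (0 of 17 past the threshold alone, adjusted p = 0.0137, and adjusted p = 0.263 with an estimated correlation), and the call was lost without Tfh 23 (0.0678) or 34 (0.177). With the stromal runs as a batch term the counts were 0 in Tfr, 1 in Treg and 1 in Tfh. The 27 libraries gave 101, 5 and 42 with 1 PBS library per cell type, which was assumed to vary like the other groups, and the 15 others gave 1 in Tfr and 3 in Treg. The count in Treg was 2 without Treg 18, 19 without Treg 33, 3 without Treg 36 and 0 without Treg 22 or 26. The count in Tfr was 1 without Tfr 28 or 35, and in Tfh 2 without Tfh 37 and 1 without Tfh 41. Leaving out the 3 libraries that stood apart, or fitting only the groups compared, gave 0 in Treg by edgeR.

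MPLA was compared with PBS to ask the same of ovalbumin with MPLA. In Treg, Atp6v1h, a subunit of the proton pump that acidifies lysosomes (chromosome 1, 5082978 to 5163213), stood at 97.4 ± 32.4 CPM in MPLA and 18.5 ± 8.88 in PBS (n = 4 and 3, 2.40, SE 0.45, adjusted p = 0.0264). Ncaph2 stood at 161 ± 9.56 against 55.0 ± 7.22 CPM (1.55, SE 0.29, adjusted p = 0.0264). Both calls were lost without Treg 40 (adjusted p = 0.886 for Atp6v1h and 0.422 for Ncaph2), Treg 36 (0.132 and 0.208), Treg 2 (0.0973 and 0.0977), Treg 6 (0.158 and 0.136) or Treg 14 (0.101 for each), and Ncaph2 without Treg 10 (0.0529). In Tfr and Tfh, edgeR called 0 genes. Unadjusted p was under 0.05 for 1080 genes in Tfr, 991 in Treg and 566 in Tfh. DESeq2 called 290, 208 and 119 genes, and limma with TPM 6, 5 and 0. Cell cycle genes were lower in Tfr of MPLA (0 of 30 past the threshold alone, adjusted p = 0.0237, and adjusted p = 0.916 with an estimated correlation). The call was lost without Tfr 8 (0.0663) or 16 (0.0519), and without Tfr 38 the direction reversed (0.983). With the stromal runs as a batch term the counts were 0 in Tfr, 2 in Treg and 0 in Tfh. The 27 libraries gave 125, 0 and 42, and the 15 others 0 in Treg. Without Treg 33 the count in Treg was 12, without Treg 10 it was 1, without Tfr 35 that in Tfr was 1, and that in Tfh was 2 without Tfh 37 and 1 without Tfh 41. In Treg, no filter on low counts (adjusted p = 0.0563 for both genes), only the groups compared, or leaving out the 3 libraries that stood apart gave 0.

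OC was compared with MPLA to set the adjuvants against each other. In Treg, Id2 was higher in OC, at 184 ± 132 against 43.0 ± 11.7 CPM (n = 4 and 4, 2.10, SE 0.34, adjusted p = 0.00292), and not without Treg 30 (1.49, adjusted p = 0.101). Trp53i13 was lower in OC, at 0.142 ± 0.284 against 9.30 ± 7.29 CPM, and its call was lost without Treg 2, 6, 18, 22 or 26 (adjusted p = 0.105, 0.161, 0.133, 0.185 and 0.103). By edgeR, 0 genes passed in Tfr, Tfh and Teff. Unadjusted p was under 0.05 for 981 genes in Tfr, 1072 in Treg, 681 in Tfh and 1123 in Teff. DESeq2 called 139, 155, 82 and 237 genes, and limma with TPM 0, 2, 2 and 2. In Treg, Th1 genes (adjusted p = 0.00946, and adjusted p = 0.102 with an estimated correlation), Tfh-repressed genes (adjusted p = 0.017, and adjusted p = 0.102 with an estimated correlation) and interferon stimulated genes (adjusted p = 0.017, and adjusted p = 0.285 with an estimated correlation) were higher in OC. Without Treg 30, Th1 (0.495) and interferon stimulated genes (0.796) were not called, nor the latter without Treg 2 (0.0735) or 14 (0.0701), nor Tfh-repressed genes without Treg 2 (0.0735) or 22 (0.0815). In Tfh, chemokine receptors and migration were lower (median -0.25, adjusted p = 0.0296, and 0.0282 with an estimated correlation) and B cell genes higher (adjusted p = 0.04, and adjusted p = 0.417 with an estimated correlation). The B cell call came with Tfh 31, which held 2206 CPM of these genes, and without it the direction reversed (0.998). It was also lost without Tfh 3, 15 or 19 (0.0927, 0.181 and 0.0626), and that of chemokine receptors without Tfh 15, 19 or 31 (0.0611, 0.0626 and 0.116). In Teff, cell cycle genes (median 1.98, adjusted p = 2.39e-07), myeloid and dendritic genes (adjusted p = 0.00904) and suppressive function genes (adjusted p = 0.0487) were higher and naive and central memory genes (adjusted p = 0.0395) lower. With an estimated correlation these 4 had adjusted p = 0.221, 0.266, 0.221 and 0.221. Without 1 library, the cell cycle call held. Myeloid genes were not called without Teff 9 or 17 (0.0967 and 0.0805), suppressive function genes without Teff 1, 9, 13, 17, 21 or 29 (0.0658 to 0.344) and naive genes without Teff 1, 9, 17, 25 or 29 (0.0613 to 0.155). With the stromal runs as a batch term the counts were 0 in Tfr, 2 in Treg, 0 in Tfh and 0 in Teff. The 27 libraries gave 0, 0, 0 and 0, and the 15 others 1 in Treg and 19 in Teff with 1 library per group. Without Tfr 24 or the 3 libraries that stood apart, Tfr gave 1 gene. Without Treg 18 the count in Treg was 4, and it was 1 without Treg 2, 22 or 30, without the 3 libraries or with no filter. Only the groups compared gave 0 in Treg, and without Teff 1 that in Teff was 1.

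**Figure D5:**
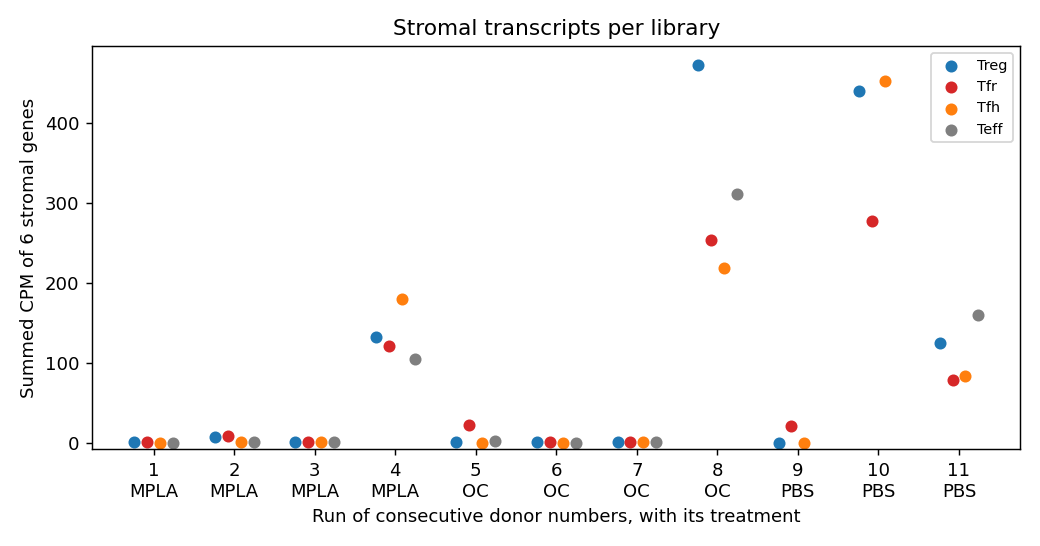
Summed CPM of 6 stromal genes in each library, by run of consecutive donor numbers with its treatment, with color for cell type. All libraries of runs 4, 8, 10 and 11 lie between 79.0 and 472, and all others between 0 and 22.6.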

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

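The tests of what the stromal transcripts come from were chosen after the result was seen.

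In 8 groups of 4 libraries, 1 library lay far from the other 3 in the summed CPM of 6 stromal genes, with a gap to the nearest library, over the range, above Dixon's critical value. The values were 105 in Teff of MPLA (donor number 13), 131.8 in Treg of MPLA (14), 179.1 in Tfh of MPLA (15), 121.4 in Tfr of MPLA (16), 310.9 in Teff of OC (29), 472.2 in Treg of OC (30), 218.9 in Tfh of OC (31) and 253.8 in Tfr of OC (32). Their groups' other libraries ran from 0 to 22.6. Of 44 tests of a value in a group, 9 found such a library, where chance gives about 5%. The 8 named here come from 2 runs of donor numbers and are not independent of each other.

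Treatment as the whole cause of the stromal transcripts is excluded, since 3 of 3 treatments held libraries on both sides of the gap, and depth is excluded, since the median total of the 15 libraries was 0.949 of that of the 27 others. RNA of stromal cells is a candidate explanation: of a second list of 22 stromal genes, 19 were higher in the 15 libraries and 0 lower, against 351 of 14493 genes higher and 10 lower in all, and the gate on Cd45 would remove such cells. None of the 22 is in a list fixed beforehand, and 0 had a mean CPM of at least 10 in the 27 other libraries. Free RNA in the sorted drop, a few sorted stromal cells and a batch of sorting or library preparation that the runs follow cannot be told apart here. Treatment was the only biological explanation tested.

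Trp53i13 was 0.593 CPM in Treg of OC with donor number 30 and 0 in the other 3 libraries of that group. With 3 libraries at 0, any value above 0 stands apart in this way, so it says nothing more about that library.

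The difference of Tfr from Treg in Ncaph2 was smaller in MPLA than in PBS by a test of the difference itself (-2.14 on the log2 scale, adjusted p = 0.0402). The call was lost without any of 11 of the 14 libraries (donor numbers 2, 4, 6, 8, 10, 14, 16, 36, 38, 40 and 42, adjusted p between 0.0726 and 0.23, with the difference between -2.15 and -1.92), with the runs as a block (0.164), with no filter on low counts (0.115), with a random draw of 0.5 of the counts (0.0994), with only the groups compared (0.95), without the 3 libraries that stood apart (0.244), in the 27 libraries (0.741) and in the 15 (0.808).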

How the results depend on the processing

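The 6 alternatives chosen after the data were seen are listed above. Of 164 named gene results, 163 kept their direction in every alternative that gave a value. Most were named for large or clear changes in these libraries, so this is a weak test. Of 5473 alternative values, 5283 kept direction and side of the threshold, 2898 of these with 1 library left out. The call was lost in 183 (105 in the 15 libraries) and gained in 6. Bcl6 in Tfr against Tfh, with no call in either, reversed to -0.21 in the 15 libraries. Of 98 list calls among 460 list tests, 62 held with an estimated correlation and 80 with fry. Without any 1 library 68 of the 98 held (65 of 80 between cell types), 30 were lost without at least 1, and 2 of these reversed: cell cycle genes in MPLA against PBS in Tfr without Tfr 38 (adjusted p = 0.983, range 0.000193 to 0.983) and B cell genes in OC against MPLA in Tfh without Tfh 31 (0.998, range 0.000289 to 0.998). List medians kept their sign with median-of-ratios size factors and with DESeq2 in 98 of 98 called lists. With TPM, which moved the median of all genes, 2 flipped, and 1 did relative to that median. Counts of genes with median-of-ratios size factors, the stricter CPM filter and a log2 fold change of at least 1 stayed within 1.5 times. Where the other alternatives below moved a count, the cause was not tested, unless fewer libraries or fewer treatments, by construction, leave less to call. DESeq2 made many false calls in simulated data, which bears on its higher counts.

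With the 27 libraries, Tfr against Treg fell to 655 and Tfr against Tfh to 501. OC against PBS gave 101, 5 and 42 in Tfr, Treg and Tfh, MPLA against PBS gave 125, 0 and 42, and OC against MPLA gave 0 in Treg. Differences of Tfr from Treg gave 51 for OC minus PBS and 62 for MPLA minus PBS. Most of these calls were higher in the treated group (98 of 101 and 123 of 125 in Tfr), against 1 PBS library per cell type. With the 15 libraries, Tfr against Treg gave 58 as the mean and 0, 0 and 26 in MPLA, OC and PBS. Tfr against Tfh gave 68, Treg against Teff 77, Tfh against Teff 21, OC against PBS 1 in Tfr and 3 in Treg, MPLA against PBS 0 in Treg, OC against MPLA 1 in Treg and 19 in Teff, and the difference of MPLA minus PBS 0. Without the 3 libraries that stood apart, Tfr against Treg in PBS gave 92, OC against PBS and MPLA against PBS 0 in Treg, OC against MPLA 1 in Tfr and 1 in Treg, and the difference of MPLA minus PBS 0. The batch term gave 1 in OC against PBS in Tfh.

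Depth was tested by a random draw of 0.5 of the counts of each library, 1 time. The counts for cell types stayed within 1.5 times, with 1151 for Tfr against Treg (1079 of them among the 1149), 208, 277 and 200 in MPLA, OC and PBS, 776 for Tfr against Tfh, 505 for Treg against Teff and 302 for Tfh against Teff. Between treatments, OC against PBS and MPLA against PBS gave 0 in Treg, OC against MPLA gave 1 in Treg and the difference of MPLA minus PBS gave 0. The folds of the genes that lost their call moved little in Treg of MPLA against PBS (Atp6v1h 2.31, adjusted p = 0.0723, and Ncaph2 1.53, 0.0723) and in the difference (Ncaph2 -2.12, 0.0994). Trp53i13 had -6.02 (0.0636) in OC against PBS and -4.89 (0.149) in OC against MPLA. Other alternatives also end these calls, so whether depth limits them is open.

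With MPLA and OC only, Tfr against Treg gave 751 and Tfr against Tfh 486. With only the groups compared, Tfr against Treg gave 107 in OC and 13 in PBS, each treatment comparison in Treg gave 0, and the difference of MPLA minus PBS gave 0. With no filter on low counts, MPLA against PBS in Treg gave 0, OC against MPLA in Treg 1 and the difference of MPLA minus PBS 0. Non-robust dispersions gave 1 in OC against PBS in Tfh. The runs of consecutive donor numbers hold 1 library of each cell type of 1 treatment, and their libraries correlated by 0.0304 on average after the groups were removed (0.0073 to 0.0921 by run, and -0.0105 between runs), below the 0.1 that would have paired them. With the runs as a block, the difference of MPLA minus PBS gave 0, Tfr against Treg gave 947 as the mean and 226, 288 and 208 by treatment, Tfr against Tfh 639, Treg against Teff 460 and Tfh against Teff 316.

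DESeq2 called 662, 693 and 890 genes for Tfr against Treg in MPLA, OC and PBS, 1270 for Tfr against Tfh, 1072 for Treg against Teff and 696 for Tfh against Teff. It called 200, 240 and 111 for OC against PBS and 290, 208 and 119 for MPLA against PBS in Tfr, Treg and Tfh, 139, 155, 82 and 237 for OC against MPLA in Tfr, Treg, Tfh and Teff, and 206, 238 and 162 for the differences OC minus PBS, MPLA minus PBS and OC minus MPLA. With log2(TPM + 1), limma called 377, 490 and 403 for Tfr against Treg by treatment, 1 and 5 for OC against PBS in Tfr and Treg, 6 and 5 for MPLA against PBS, 2 for OC against MPLA in Tfh and 2 in Teff, and 1, 3 and 3 for the differences. With log2(TPM + 0.1) these were 329, 443 and 381, then 1 and 11, 5 and 8, 1 for OC against MPLA in Tfr, and 2, 2 and 2. With no filter on TPM they were 350, 427 and 345, then 2, 11 and 2 for OC against PBS in Tfr, Treg and Tfh, 14, 11 and 3 for MPLA against PBS, 2, 3 and 2 for OC against MPLA in Tfr, Tfh and Teff, and 1, 4 and 1.

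Leaving out 1 library at a time gave 122 to 166 genes for Tfr against Treg in MPLA, 146 to 261 in OC and 66 to 222 in PBS. OC against PBS ranged from 0 to 1 in Tfr, 0 to 19 in Treg and 0 to 2 in Tfh, and MPLA against PBS from 0 to 1, 0 to 12 and 0 to 2. OC against MPLA ranged from 0 to 1 in Tfr, 1 to 4 in Treg and 0 to 1 in Teff. The differences ranged from 0 to 9 for OC minus PBS, 0 to 5 for MPLA minus PBS and 0 to 1 for OC minus MPLA. The means stayed within 1.5 times, at 913 to 1143 for Tfr against Treg, 543 to 724 for Tfr against Tfh, 413 to 477 for Treg against Teff and 243 to 296 for Tfh against Teff.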

Other observations

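The tests chosen after the result was seen were those of ribosomal protein genes, of a mixture of cells and of RNA of other cells in Tfr, that of the OC treatment for S100a8, and the splits for the differences of Tfr from Treg.

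Ribosomal protein genes, a group chosen after their values were seen, were lower in Tfr than in Treg almost as a whole. Of 74 tested genes of the cytosolic ribosome, 70 were lower and 0 higher in Tfr (median log2 fold change -0.81), among 565 genes lower in all (one-sided Fisher's exact p = 3.15e-95, with genes that are not independent). By treatment, 35 were lower in MPLA, 50 in OC and 30 in PBS. They took 6.54% ± 0.651 of the counts of tested genes in Tfr (SD, n = 11, 5.71% to 7.40%) and 10.8% ± 1.72 in Treg (n = 11, 8.74% to 13.8%), with no overlap between libraries. Tfh (7.06% ± 0.818, n = 11) lay near Tfr, where 1 of the 74 was lower in Tfr than in Tfh and 0 higher (median -0.07). Teff took 8.65% ± 0.852 (n = 9), with 7 genes higher in Treg and 6 lower in Tfh than in Teff. The number lower in Tfr than in Treg was 69 with median-of-ratios size factors, 71 with DESeq2, 68 with TPM (median -0.62, where all genes moved by 0.14) and 57 in the 27 libraries without stromal transcripts. In those 27 the numbers by treatment fell to 12 in MPLA, 36 in OC and 1 in PBS, which then had 1 library per cell type, while the medians stayed at -0.66, -0.90 and -0.84. Reads of ribosomal genes are shared with their many pseudogenes, which was not tested.

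Tfr held a set of transcripts above or below both relatives. Of 14493 genes, 143 were higher and 147 lower in Tfr than in both Treg and Tfh, where 16.4 and 14.5 would be expected if the comparisons were independent. The same Tfr libraries enter both comparisons. With the Tfr libraries split between them, 59 and 71 genes were still higher in both for the 2 assignments, so sharing libraries is not the whole cause. The number expected by chance for the split was not computed. In 5 simulations where every gene had the same mean in all libraries, 0 genes were higher in both. With no gene changed almost none can be called, so the simulations decide nothing here. In 18 genes every Tfr library lay above every Treg and Tfh library, and in 13 genes below. Among the 18, chosen after their values were seen, were Cd83, an activation marker (650.4 ± 235 CPM in Tfr, 166 in Treg and 34.4 in Tfh), Ikzf2, the transcription factor Helios (768 ± 96.0, 421 and 154), and Cst7, an inhibitor of proteases (508 ± 146, 175 and 131). Among the 13 were the chromatin organizer Satb1 (11.5 ± 11.8, 249 and 140) and the transcription factor Lef1 (107 ± 18.7, 255 and 240).

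A mixture of the mean Treg and mean Tfh profiles in the Tfr gate is excluded as the source of these 18 genes. Such a mixture lies between its parts, and the highest of 30 simulated mixtures gave 0 such genes. A mixture that holds a subset of Treg or Tfh cells, unlike these means, was not simulated and stays open. RNA of other cells stays open. Of 78 tested members of the 5 lists of other cells, 0 were among the 143, but chance alone gives 0.770, only 28 had a mean CPM of at least 10, and other cell types were not tested.

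Most genes called in 2 comparisons with no library in common moved the same way. Such comparisons still draw on the same runs of donor numbers, and the expected numbers take them as independent. Tfr against Treg and Tfh against Teff shared 124 genes, of which 102 moved the same way (82.3%), with 45 higher in both (4.88 expected) and 57 lower in both (7.80 expected). Of all 321 genes called in Tfh against Teff, 71.7% had the same sign in Tfr against Treg. Opposite directions were seen in 22, such as S1pr1 and Cxcr3, chosen after their values were seen. Tfr against Tfh and Treg against Teff shared 165 genes, of which 140 moved the same way (84.8%), with 75 higher (6.88 expected) and 65 lower (7.32 expected). Of the 530 genes called in Treg against Teff, 72.3% had the same sign in Tfr against Tfh. A shared difference of follicular cells and one of regulatory cells may be part of this, but both shares lie under the bound of 90% set for it and above the 60% that would have excluded it. The question stays open, and the gate itself fixes some of the shared genes.

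Calprotectin transcripts were high in some Tfh libraries of OC. S100a8 was 1201, 173, 3.88 and 365 CPM in donor numbers 19, 23, 27 and 31 and at most 1.73 in the 7 other Tfh libraries. An effect of OC treatment stays open: over all genes, S100a8 did not pass in Tfh for OC against MPLA (adjusted p = 0.227) or OC against PBS (adjusted p = 1, the value that decides here), where edgeR called 0 genes. S100a9 was 402, 66.9, 0.72 and 120 CPM in the same 4 libraries and at most 0.53 in the 7 others. In Treg 30, Teff 17 and Tfr 32 of OC, S100a8 was 25.4, 6.84 and 6.79 CPM and S100a9 23.1, 3.42 and 4.07. Hemoglobin Beta-s was 1761, 958 and 500 CPM there, 2009 in Tfr 20 and 42 in Tfh 19. Elsewhere S100a8 was at most 2.74 in OC and 1.95 in MPLA and PBS, where Beta-s was at most 62.3. RNA of neutrophils may be a source: 6 of 17 measured genes of a neutrophil list (20 listed, 2 in a list fixed beforehand) had their highest CPM of all 42 libraries in donor number 19 (2.38% expected by chance), among them Ngp at 301 and Camp at 101 CPM. Other libraries with high S100a8 differed. In Tfh 23, Ngp, Ltf, Lcn2 and Retnlg were 0 and Camp 0.13, and in 31 Retnlg was 112, Ngp 12.6 and Camp 5.03. The 6 genes are fewer than the 9 that would have settled it, with Mpo, Prtn3 and Il1b near 0 in all libraries. The gate on Cd3 and Cd4 would remove such cells. Both explanations may hold together and stay open.

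Teff expressed Id2 at 2107 ± 529 CPM (n = 9) and Zbtb16 at 53.7 ± 39.5. In the same libraries Cd8a was 1.51 ± 3.70, Cd8b1 8.00 ± 7.29 and the NK receptor Ncr1 3.27 ± 9.75 CPM (29.0 in Teff 5). Other members of the CD8 and NK list were high in every Teff library, with Klrb1c at 145 to 475, Klrk1 at 64.8 to 257 and Xcl1 at 69.3 to 150 CPM. The whole list summed to 713 ± 85.1 CPM in Teff, against means of 131.5 in Treg, 74.0 in Tfr and 81.6 in Tfh. Which cells carry these transcripts was not tested.

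Other splits of the same libraries show where chance can be excluded as the source of a count of genes. For Tfr against Treg as the mean of treatments, 1 of 100 splits gave as many genes (1141 by the faster fit, highest other 657), and for Tfr against Tfh 1 of 100 (778, highest other 2). Treg against Teff had 1 of 100 (526, highest other 151) and Tfh against Teff 1 of 100 (308, highest other 66). Tfr against Treg in MPLA had 1 of 35 (195, highest other 0) and in OC 1 of 35 (260, highest other 6), so chance is excluded for these 6 counts. The splits with 657, 151 and 66 genes differ from the cell types by 1 exchange of libraries. For OC against MPLA in Treg the share was also under 0.05 (1 of 35, 2 genes, highest other 1), but this is 1 of 10 comparisons of treatments, and the count was 0 in the 27 libraries and with only the groups compared and 1 to 4 with 1 library left out. The splits thus do not settle it. For Tfr against Treg in PBS, 10 splits are too few for a share under 0.05 (1 as large, 179 genes, highest other 3).

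Chance was not excluded for OC against PBS in Treg (22 of 35 splits gave as many genes, 1 gene, highest other 75), for MPLA against PBS in Treg (5 of 35, 2 genes, highest other 3) and, with treatments exchanged within each cell type, for the difference of Tfr from Treg of MPLA minus PBS (22 of 100, 1 gene, highest other 4). Where the real count is 0, every split gives as many and the splits decide nothing. This holds for the 35 of 35 splits of OC against PBS in Tfr and Tfh (highest other 2 and 2), of MPLA against PBS in Tfr and Tfh (3 and 2) and of OC against MPLA in Tfr, Tfh and Teff (3, 0 and 5). It also holds for the 100 of 100 of the differences of OC minus PBS (highest other 19) and OC minus MPLA (1). The split with 75 genes put Treg 18, 22 and 40 against 26, 30, 33 and 36, and with it the 2 Treg libraries that stood apart on 1 side. The split with 19 genes also put Treg 22 and 40 together (with Treg 30). Whether Treg 22 and 40 account for these counts was not tested. In comparisons with PBS, a split can part all libraries of the stromal runs from the others, and it gave 2 genes for OC in Tfr, 1 for OC in Treg and 2 for MPLA in Treg (the batch term gave 0, 1 and 2), and 0 for OC in Tfh and for MPLA in Tfr and Tfh. Elsewhere splits follow the runs only in part. The widest such gave 5 genes in OC against MPLA in Teff, 3 in Tfr, 1 in Treg and 0 in Tfh (the batch term gave 0, 0, 2 and 0), and 1, 4 and 0 for the differences of OC minus PBS, MPLA minus PBS and OC minus MPLA (the batch term gave 0, 1 and 0). For cell types it gave 1 in Tfr against Treg in OC, 1 in Tfh against Teff and 0 in the 5 others.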
